A study of Homo sapiens with 6 samples.

How the data were processed

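RNA was sequenced from 6 samples of the AF22 line, 3 control and 3 knockdown, grouped by the sample titles. Per the labels' protocols, RNA was extracted with an organic reagent, treated with DNase on a column, and 700 ng of total RNA went into each library with a directional kit. The submitters' processing notes name Trim Galore 0.6.6, STAR 2.7.10a and bedtools, and the build hg38. The counting step, its strand setting and the gene annotation are not given in the sources used here. The authors deposited 1 table per sample with a read count per gene symbol, and the counts are whole numbers that were not normalised. Each table lists the same 26485 symbols, of which 23899 (90.2%) were found in GENCODE v29, used here for coordinates on GRCh38. No symbol begins with MT-. Since the strand setting is not given, reads of genes that overlap on opposite strands may not have been told apart.

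The 26485 symbols were filtered with filterByExpr of edgeR 4.0.16 (R 4.3.3), which kept 13632 genes holding between 99.858% and 99.869% of each library's counts. Counts were scaled by TMM (factors 0.9797 to 1.015), and knockdown was compared with control by the edgeR quasi-likelihood test with no covariate. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM are counts scaled to the TMM-adjusted library size, given as mean ± SD over 3 libraries. With 3 counts as the floor, a gene at 0 in a library allows up to 0.259 to 0.42 CPM. A fold against a group with no counts is a lower bound against 3 counts over that group, and leaves out the counting error of the other group. Ratios of counts have exact 95% binomial intervals, and intervals and floors cover counting error only.

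Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for the 32 of 35 lists with 3 or more tested genes, and adjusted over these lists. The lists were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives, apart from those called added. The rule named COMMD3, COMMD3-BMI1 and BMI1, and the 12 genes with the largest rise and the 12 with the largest fall among genes with adjusted p under 0.05, mean CPM of 5 or more and no overlap between the groups' libraries. It passed over symbols that begin with LOC, LINC, MIR, SNOR or RNU or hold AS1 or a dot. It also named up to 4 called members with the smallest adjusted p of each list, 1 well-expressed member of a list with none called, and the 5 genes with the smallest p. The 140 genes it gave were recomputed under each alternative, and part of them are named in the text. After the data were seen, 7 lists were added: class I and class II antigen presentation, chemokines of the interferon response, interferons, RNA and DNA sensors and adaptors, endothelial-associated genes, and leukocyte markers.

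The other analyses fixed beforehand were RLE, upper-quartile and library-size scaling, no filter, a filter of 1 CPM or more in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library in turn, a 1.5-fold threshold, an adjusted p under 0.01, fry, and camera with estimated correlations. Added alternatives were removal of each library's trend on transcript length and GC content (loess span 0.5; known for 94.4% of tested genes), camera on ranks, removal of genes whose 3′ UTR holds TCATCCA, and removal of the interferon list from the background. For each pair of replicates, a chi-square statistic over genes with 10 or more counts was between 1.23 and 1.994 per degree of freedom, so no pair agreed within sampling noise and each library was counted once.

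The 3′ UTR scan was chosen after the data were seen. It took the transcript with the longest 3′ UTR of each gene in GENCODE v29, for 12072 tested genes with 50 bases or more. For each of 16384 words of 7 bases it regressed log2 fold changes, limited to between −1 and 1, on the presence of the word, adjusted for 3′ UTR length and GC content. A first version without that limit, leaving out genes with a log2 fold change of 1.5 or more in size, gave the same lowest word (z = −17.1). For the comparison of sites, the word was chosen in 6036 genes drawn at random and measured in the other 6036 by regression of the limited log2 fold changes, adjusted for length and GC content of the 3′ UTR and coding sequence, and the parts were then exchanged. Intervals of these steps are 95% percentile intervals from 2000 bootstrap draws over genes. This step and the figures used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

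The gene tests, camera and the word scan were tested on simulated data. With counts drawn for 13630 genes from the means and library sizes of the knockdown and control comparison, and 200 genes changed, edgeR recovered 60% of those changed 1.2-fold, 86% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, with 8 false calls. Camera called 20 of 20 simulated lists shifted by 1.2-fold and none of 20 that were not shifted, with either correlation. The simulated genes were drawn independently, so this does not measure list calls that come from genes varying together, and in the 9 other splits of the real libraries camera with the preset correlation called 3 to 8 lists. The scan ranked first 20 of 20 words planted with a log2 fall of 0.15.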

Results

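RNA was measured by sequencing in AF22, an established human cell line of neuroepithelial-like neural stem cells derived from induced pluripotent stem cells. The 6 libraries fell into 2 groups of 3. Control cells carried a control short hairpin RNA (shControl), a small RNA that the cell turns into a guide for lowering transcripts. Knockdown cells are labelled as a knockdown of COMMD3 and COMMD3-BMI1, and the labels do not describe the reagent used. Each library was a table of read counts for 26485 gene symbols. The totals were 11579849, 8798045 and 7294687 counts in control replicates 1 to 3, and 9421178, 8574066 and 9692967 in knockdown replicates 1 to 3. The 10 most abundant genes took between 1.26% and 1.36% of the counts of a library. The first principal component held 70.4% of the variance of log2 CPM and separated the 2 groups. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

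The comparison asked which transcripts differed between human neural stem cells labelled as this knockdown and control cells. COMMD3, which encodes a subunit of the Commander complex that sorts membrane proteins at endosomes, was 2.585-fold lower in knockdown than in control. Its level was 29.67 ± 2.04 CPM in control and 11.55 ± 1.22 CPM in knockdown (SD, n = 3 each), a log2 fold change of −1.37 (SE 0.0996, edgeR adjusted p = 2.34e-12). All 3 knockdown libraries, at 12.9, 11.3 and 10.5 CPM, lay below the lowest control library at 27.6 CPM. BMI1, which encodes a subunit of polycomb repressive complex 1, had 110.2 ± 2.41 CPM in control and 104.8 ± 1.79 CPM in knockdown, and this difference did not pass the test (log2 fold change −0.07, SE 0.0448, edgeR adjusted p = 0.206). The readthrough gene COMMD3-BMI1, which joins exons of both, was listed at 0 in all 6 libraries, so its own level was not measured here.

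In GRCh38 (GENCODE v29), COMMD3 (ENSG00000148444) lies on chromosome 10 from 22315974 to 22320308 on the plus strand. COMMD3-BMI1 (ENSG00000269897) runs from 22316388 to 22329542 and BMI1 (ENSG00000168283) from 22321211 to 22331484, both on the same strand. COMMD3-BMI1 has no exon base of its own among 1419, since each is also an exon base of COMMD3 or BMI1. COMMD3 has 923 of 1342 exon bases to itself and BMI1 2428 of 3428. The deposited counts therefore cannot separate the readthrough transcript from the 2 genes it joins, and part of the COMMD3 and BMI1 counts may come from it. EIF4A1, a translation factor that every cell uses, was also listed at 0 in all 6 libraries, while the overlapping readthrough SENP3-EIF4A1 had 613.8 ± 22.5 CPM in control and 613.5 ± 10.8 CPM in knockdown (SD, n = 3 each).

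**Figure D1:**
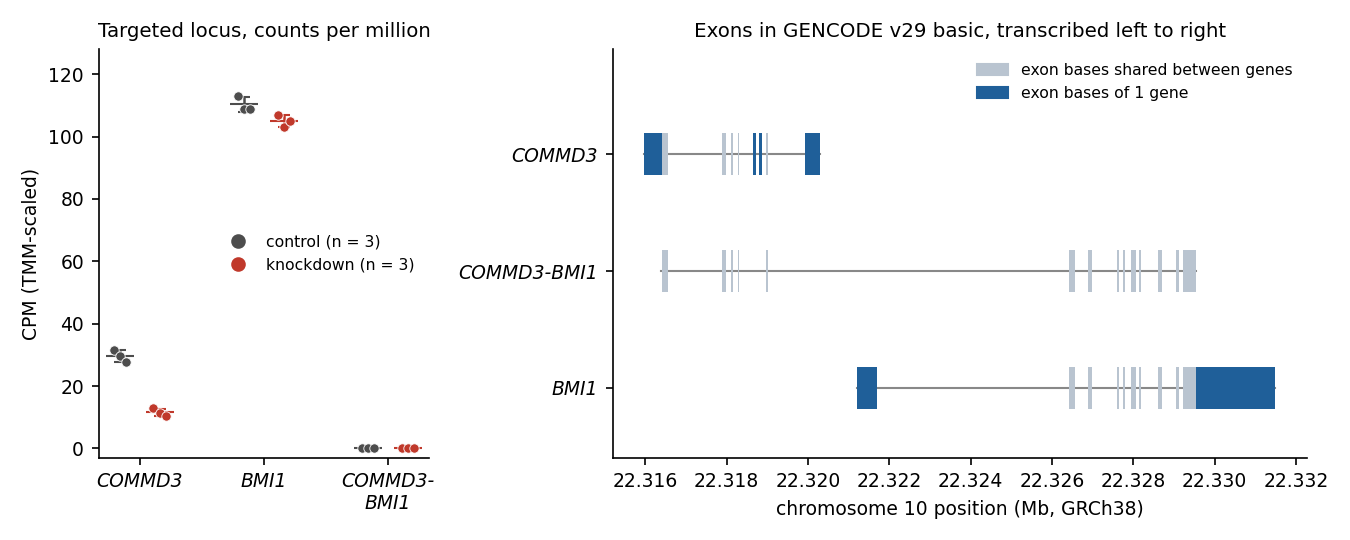
Left, CPM of COMMD3, BMI1 and COMMD3-BMI1 in each control (grey) and knockdown (red) library, with horizontal bars for the mean and error bars for the SD (n = 3 each). COMMD3 lies at 27.6 CPM or more in control and 12.9 CPM or less in knockdown, and COMMD3-BMI1 at 0 throughout; right, exons of the 3 genes on chromosome 10 in GRCh38, with bases that belong to 1 gene in blue and bases shared between genes in grey.

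Across the transcriptome, the strongest differences were higher levels of interferon-stimulated genes in knockdown cells, beside many small differences in both directions. Of 13632 genes tested, 4545 (33.3%) changed, 2084 higher and 2461 lower in knockdown (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median fold of the changed genes was 1.2. At 1.5-fold or more, 317 genes were higher and 351 lower, and at 2-fold or more, 141 were higher and 64 lower. The 71 genes that changed 4-fold or more were higher in knockdown. The 3 control and 3 knockdown libraries did not overlap for 4266 of the 4545 changed genes, and for 44.3% of all tested genes, where chance gives 10%. DESeq2 called 2877 genes, of which 2876 were among the 4545.

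Genes of the interferon response rose together. Of 35 tested members of the list fixed beforehand, 34 were higher in knockdown, with a median log2 fold change of 3.97, or 15.7-fold. The median was the same with the 1 member that had no control counts set at its lower bound. MX1, a GTPase that restricts viruses, rose from 2.63 ± 0.389 to 247.9 ± 18.8 CPM (SD, n = 3 each), a log2 fold change of 6.58 (SE 0.095, edgeR adjusted p = 1.43e-30). IFIT1, which binds foreign RNA, rose from 6.68 ± 0.659 to 267.5 ± 31.3 CPM. OAS3, which makes the oligoadenylate messenger that activates RNase L, rose from 5.83 ± 0.661 to 273.7 ± 34.3 CPM. IFI44L rose from 7.46 ± 1.68 to 216.5 ± 15.1 CPM and IFI6 from 22.65 ± 3.22 to 360.2 ± 35.8 CPM. Adjusted over the list alone, the same number of members, 34, was higher. ISG20 was the member that did not pass (log2 fold change 0.39, edgeR adjusted p = 0.338), and it is named after its values were seen. The list was called by camera (adjusted p = 2.13e-38), and not when the correlation between its genes was estimated (adjusted p = 0.157 with an estimated correlation).

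Of the 12 genes with the largest rise among changed genes with a mean CPM of 5 or more, no overlap between the groups’ libraries and a symbol the naming rule keeps, 10 were on the interferon list, and the other 2, EPSTI1 and SAMD9L, are known as interferon-inducible genes. EPSTI1 rose from 0.163 ± 0.142 to 42.83 ± 4.05 CPM and SAMD9L from 0.334 ± 0.298 to 20.1 ± 4.26 CPM (SD, n = 3 each). OAS2 had 4 counts over the 3 control libraries and 4403 over the knockdown libraries, a log2 fold change of 9.95 that became 11 without control replicate 1. OASL had no counts in control and 330 in knockdown, so it was at least 108-fold higher against a floor of 3 counts over the group. XAF1, IFI44, IFI27, BST2 and HERC6 rose by between 4.90 (HERC6) and 7.15 (XAF1) on the log2 scale. OAS1 was passed over by the naming rule because its symbol holds the letters AS1, and is given after its values were seen: 5 counts in control and 3155 in knockdown, with a log2 fold change of 9.17. Among 14 leukocyte markers, 4 were expressed enough to be tested and none was higher by edgeR, at an unadjusted p under 0.05, or by DESeq2.

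**Figure D2:**
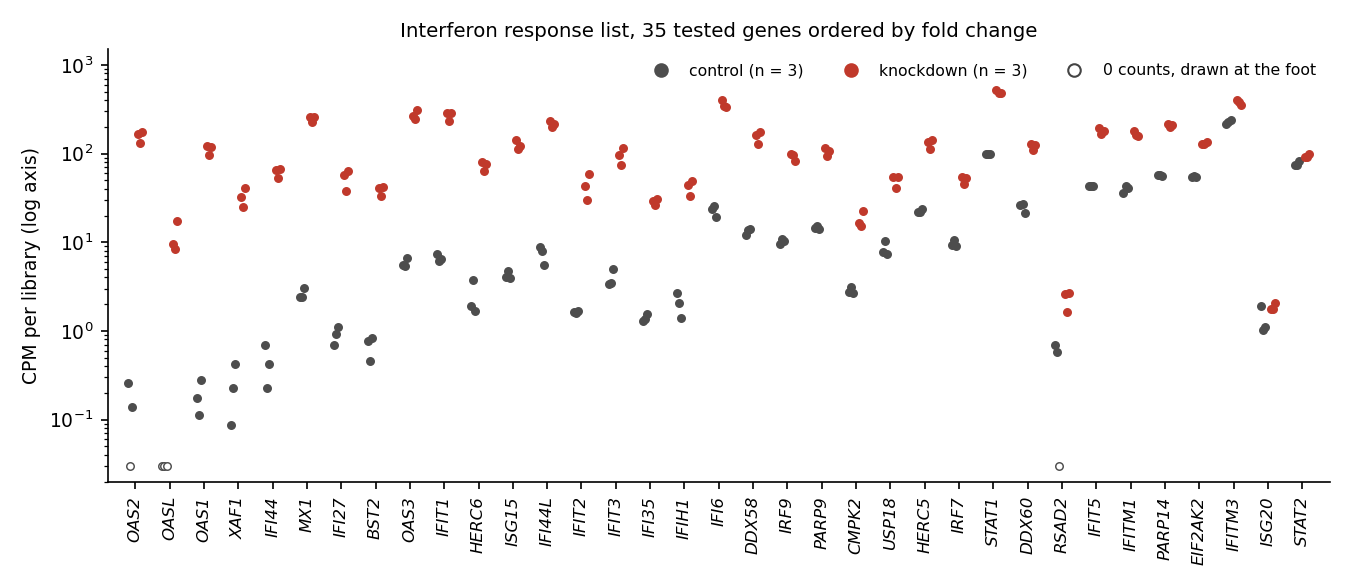
CPM on a log axis in each control (grey) and knockdown (red) library for the 35 tested genes of the interferon response list, ordered by fold change; open circles at the foot are libraries with 0 counts. Every knockdown library lies above every control library for 34 of the 35 genes, ISG20 being the exception.

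The genes that fell did so by smaller folds. Among changed genes with a mean CPM of 5 or more, no overlap between the groups’ libraries and a symbol the naming rule keeps, the 12 with the largest fall had log2 fold changes from −1.44 to −1.04 and included COMMD3 itself. ZDHHC22, a palmitoyltransferase, fell from 11.1 ± 1.16 to 4.05 ± 0.379 CPM (SD, n = 3 each; log2 fold change −1.44, SE 0.156, edgeR adjusted p = 1.51e-08). The G protein subunits GNG4 and GNAL fell to 13.82 ± 1.72 from 34.87 ± 2.5 CPM and to 23.76 ± 3.16 from 51.11 ± 0.45 CPM. Of the exon bases of GNAL, 26.6% are also covered by a gene on the other strand. The synaptic vesicle protein SV2A fell from 110.5 ± 6.89 to 53.48 ± 3.10 CPM, and the nicotinic receptor subunit CHRNB2 from 17.06 ± 2.05 to 7.69 ± 1.15 CPM. The receptor tyrosine kinase ERBB3 fell from 12.22 ± 0.925 to 5.16 ± 0.88 CPM and the transcription factor EGR2 from 12.95 ± 0.879 to 5.62 ± 0.234 CPM. MXD1, CPNE4, SLITRK1 and CD93 fell by between 1.13 (CD93) and 1.26 (MXD1) on the log2 scale. The 3′ UTRs of 5 of these 12 genes (ZDHHC22, GNG4, ERBB3, CD93 and GNAL) hold the 7-base word TCATCCA, which was singled out after the data were seen.

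Most tested genes of the 2 cell cycle lists were lower in knockdown. Of 28 tested genes of G1/S and DNA replication, 19 fell and 9 did not pass, with a median log2 fold change of −0.21 (camera adjusted p = 5.32e-06; adjusted p = 0.522 with an estimated correlation). UHRF1, which keeps DNA methylation through replication, fell from 150.6 ± 1.10 to 103.1 ± 3.10 CPM, CCND2 (cyclin D2) from 900.0 ± 17.2 to 688.6 ± 25 CPM and the replicative helicase subunit MCM4 from 345.2 ± 7.49 to 275.7 ± 11.2 CPM (SD, n = 3 each). Of 26 genes of G2/M, 18 fell and 8 did not pass, with a median of −0.16 (camera adjusted p = 7.55e-05; adjusted p = 0.446 with an estimated correlation). CENPE, a kinetochore motor, fell from 139.9 ± 13.7 to 92.6 ± 5.67 CPM, MKI67 from 399.8 ± 34.9 to 269.0 ± 25.5 CPM and TOP2A from 610.0 ± 14.1 to 469.4 ± 10.1 CPM. Adjusted over the list alone, 19 genes fell in each of the 2 lists. The 3′ UTRs of UHRF1, CCND2 and MKI67 hold TCATCCA, as part of 4 such members among the 28 and 2 among the 26. Without the members that hold it, the medians stayed at −0.21 and −0.16.

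Most tested genes of the sterol list and of the FGF-ERK target list were also lower. Of 25 tested genes of cholesterol synthesis and uptake, 15 fell and 10 did not pass, with a median log2 fold change of −0.18 and the same 15 lower when adjusted over the list alone (camera adjusted p = 0.000258; adjusted p = 0.157 with an estimated correlation). The sterol carrier STARD4 fell from 138.1 ± 6.28 to 97.44 ± 5.44 CPM and CYP51A1, a demethylase of the sterol pathway, from 278.2 ± 9.36 to 234.2 ± 3.55 CPM (SD, n = 3 each). Of 18 FGF-ERK targets, 12 fell and 6 did not pass. Adjusted over the list alone, 13 were lower and 1 was higher (camera adjusted p = 0.0288; adjusted p = 0.563 with an estimated correlation). ETV1, an ETS transcription factor, fell from 215.4 ± 2.1 to 174.3 ± 8.45 CPM and EGR1, an immediate early gene, from 85.13 ± 7.97 to 68.71 ± 8.26 CPM. The FGF-ERK call was lost without control replicate 3 (adjusted p = 0.0994) and without knockdown replicate 1 (adjusted p = 0.0598).

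The lists of stress response and oxidative phosphorylation genes were called higher, though most of their members did not pass as higher on their own. Of 25 tested genes of the unfolded protein and integrated stress responses, 12 rose, 1 fell and 12 did not pass, and the counts were alike when adjusted over the list alone (camera adjusted p = 0.0139; adjusted p = 0.522 with an estimated correlation). The members that rose include CHAC1, which degrades glutathione, from 21.82 ± 4.51 to 37.39 ± 4.04 CPM, asparagine synthetase (ASNS), from 181.9 ± 4.07 to 254.8 ± 21.3 CPM, and the transcription factor ATF3, from 81.66 ± 3.57 to 109.1 ± 4.05 CPM (SD, n = 3 each). These 3 are known targets of ATF4. HSPA5, a chaperone of the unfolded protein response, had a log2 fold change of 0.09 (edgeR adjusted p = 0.108), and is named after its values were seen. Of 26 nuclear genes of oxidative phosphorylation, 11 rose and 15 did not pass, with 13 higher when adjusted over the list alone (median log2 fold change 0.12; camera adjusted p = 0.00232; adjusted p = 0.522 with an estimated correlation). UQCRC1, of complex III, rose from 138.1 ± 5.10 to 156.6 ± 1.22 CPM. None of the symbols in the files belongs to the list of mitochondrially encoded genes.

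Of 43 cytosolic ribosomal protein genes, 7 rose, 1 fell and 35 did not pass, or 4 and 1 when adjusted over the list alone (median log2 fold change 0.06; camera adjusted p = 0.0288; adjusted p = 0.868 with an estimated correlation). RPL18 rose from 186.8 ± 6.14 to 211.9 ± 4.09 CPM and RPLP0 fell from 564.6 ± 15.3 to 494.7 ± 17.3 CPM (SD, n = 3 each). Ribosomal protein genes have many near-identical pseudogenes, so their counts are uncertain where reads match several copies. The call was lost without control replicate 2 (adjusted p = 0.221), knockdown replicate 1 (adjusted p = 0.147) or knockdown replicate 2 (adjusted p = 0.0656), under fry (adjusted p = 0.237), with the length and GC trend removed (adjusted p = 0.463), and without genes whose 3′ UTR holds TCATCCA (adjusted p = 0.0766). With correlations estimated for each list, none of the 8 list calls held, while 3 lists had an unadjusted p under 0.05.

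**Figure D3:**
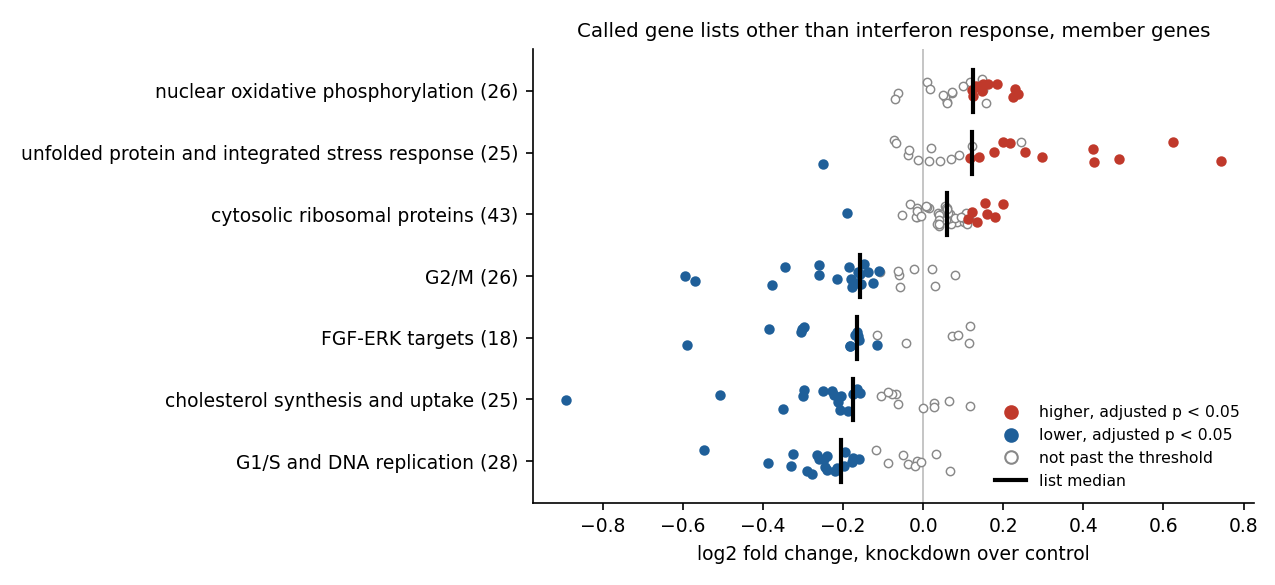
Log2 fold change of knockdown over control for each tested member (points) of the 7 called gene lists other than the interferon response, with the list median as a black bar and the number of tested genes in brackets; red and blue points passed the edgeR test as higher and lower, open points did not. The medians run from −0.21 for G1/S and DNA replication to 0.12 for nuclear oxidative phosphorylation.

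Genes around the function of the targeted locus moved in both directions. In polycomb repressive complex 1, to which BMI1 belongs, 3 of 19 tested genes rose and 3 fell, or 5 and 4 when adjusted over the list alone (camera adjusted p = 0.653). RING1 rose from 40.15 ± 3.14 to 48.78 ± 1.45 CPM and PCGF3 fell from 128.4 ± 2.63 to 105.8 ± 4.76 CPM (SD, n = 3 each). In polycomb repressive complex 2, 4 of 11 tested genes fell, also when adjusted over the list alone (camera adjusted p = 0.216). JARID2 fell from 167.8 ± 2.32 to 121.5 ± 3.41 CPM, and SUZ12 and EZH2 fell by 0.36 and 0.25 on the log2 scale. Of 8 CDK inhibitor genes, 3 rose, also when adjusted over the list alone (camera adjusted p = 0.228). CDKN2A, a polycomb target that encodes p16 and p14ARF, rose from 2.98 ± 0.581 to 5.02 ± 1.28 CPM (edgeR adjusted p = 0.00789), a call lost without knockdown replicate 1 (adjusted p = 0.083). CDKN1B (log2 fold change 0.12) lost its call without control replicate 2 (adjusted p = 0.0922), control replicate 3 (adjusted p = 0.0671) or knockdown replicate 2 (adjusted p = 0.159), by DESeq2 (adjusted p = 0.101) and with the length and GC trend removed (adjusted p = 0.0692). CDKN1A had a log2 fold change of −0.05 (edgeR adjusted p = 0.426), and is named after its values were seen. Of 39 HOX genes, which polycomb complexes are known to silence, 2 were expressed enough to be tested. HOXB2 had 20.35 ± 0.941 CPM in control and 23.67 ± 1.36 CPM in knockdown (edgeR adjusted p = 0.0571), and passed when adjusted over the list alone. It also passed without knockdown replicate 3 (adjusted p = 0.0347), with library-size scaling (adjusted p = 0.0432), with upper-quartile scaling (adjusted p = 0.0498) and with the replicate number as a block (adjusted p = 0.039).

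Of 16 tested COMMD and Commander genes, COMMD3 among them, 4 rose and COMMD3 fell, also when adjusted over the list alone (camera adjusted p = 0.653, higher, with a median of 0.05 and a mean of −0.04). COMMD2 rose from 78.67 ± 1.43 to 90.09 ± 1.08 CPM (SD, n = 3 each). Of 9 tested WASH and retromer genes, 2 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.761). The retromer subunit VPS35 fell from 239.2 ± 3.6 to 180.8 ± 1.83 CPM. Of the 2 that rose, SNX6 (log2 fold change 0.12) lost its call without control replicate 1 (adjusted p = 0.129), control replicate 3 (adjusted p = 0.0825), knockdown replicate 1 (adjusted p = 0.118) or knockdown replicate 2 (adjusted p = 0.0768), with no filter (adjusted p = 0.0592) and by DESeq2 (adjusted p = 0.145). Of 6 tested genes at the COMMD3-BMI1 locus and its 10p12 neighbours, 2 fell, COMMD3 and MLLT10, also when adjusted over the list alone (camera adjusted p = 0.228). The call of MLLT10 (log2 fold change −0.14) was lost without control replicate 3 (adjusted p = 0.0602), knockdown replicate 1 (adjusted p = 0.0924) or knockdown replicate 2 (adjusted p = 0.059), by DESeq2 (adjusted p = 0.0928) and with the length and GC trend removed (adjusted p = 0.0686). Of the Commander genes that rose, COMMD10 lost its call without knockdown replicate 1 (adjusted p = 0.0786) and COMMD7 by DESeq2 (adjusted p = 0.0734).

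Neural identity lists were mostly lower in their changed members but did not pass the list test. Of 22 tested neural stem cell markers, 7 fell and 2 rose, or 8 and 2 when adjusted over the list alone (camera adjusted p = 0.132). NOTCH1 fell from 160.5 ± 0.86 to 118.4 ± 12.3 CPM and SOX9 from 186.6 ± 4.35 to 149.3 ± 8.68 CPM, while HES4 rose from 4.01 ± 1.03 to 15.08 ± 2.28 CPM (SD, n = 3 each). Of 16 neuronal differentiation genes, 5 fell and 1 rose, or 7 and 1 when adjusted over the list alone (camera adjusted p = 0.124), and the list was called without knockdown replicate 3 (adjusted p = 0.0396). The neurofilament gene NEFM fell from 118.0 ± 2.18 to 75.25 ± 4.68 CPM and GAP43, a growth cone protein, rose from 31.82 ± 2.73 to 42.46 ± 0.90 CPM. Of 11 astrocyte markers, 4 fell and 2 rose, or 5 and 2 when adjusted over the list alone (camera adjusted p = 0.294). In the oligodendrocyte list 3 of 6 fell and 1 rose (camera adjusted p = 0.228), and in the neural crest and Schwann list 5 of 10 fell and 1 rose (camera adjusted p = 0.059), the same counts as when adjusted over the list alone. The neural crest and Schwann list was called without control replicate 1 (adjusted p = 0.0426) or knockdown replicate 2 (adjusted p = 0.0477). Of 10 mid- and hindbrain genes, 5 fell, with 1 more higher when adjusted over the list alone (camera adjusted p = 0.059), and the list was called without knockdown replicate 1 (adjusted p = 0.0474) or knockdown replicate 2 (adjusted p = 0.0477). Both lists were also called with library-size scaling (adjusted p = 0.0481 for each) and with the length and GC trend removed (adjusted p = 0.0463 for each). None of 17 forebrain genes was expressed enough to be tested.

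The remaining lists were not called either. Of 6 tested pluripotency markers, 3 fell and 1 rose (camera adjusted p = 0.499), and LIN28A, an RNA-binding protein of stem cells, rose from 303.6 ± 6.83 to 456.8 ± 25.4 CPM (SD, n = 3 each). Mesenchymal markers had 4 higher and 5 lower of 16 (camera adjusted p = 0.688, lower, with a median of 0.01 and a mean of −0.07), and endoderm markers 1 higher and 1 lower of 3 (camera adjusted p = 0.939). Hedgehog genes had 1 higher and 3 lower of 11 (camera adjusted p = 0.228). Wnt targets and inhibitors had 4 higher and 5 lower of 15 (camera adjusted p = 0.821, lower, with a median of 0.09 and a mean of −0.14). DKK3 fell from 75.18 ± 2.93 to 37.45 ± 2.00 CPM. Notch genes had 2 higher and 5 lower of 17 (camera adjusted p = 0.794, lower, with a median of −0.02 and a mean of 0.04). BMP and TGF-beta targets had 4 higher and 3 lower of 17 (camera adjusted p = 0.956, lower, with a median of −0.08 and a mean of 0.13). NF-kB targets had 3 higher and 4 lower of 18 (camera adjusted p = 0.939, higher, with a median of −0.03 and a mean of 0.20), and those that rose were IRF1, ICAM1 and VCAM1, which interferons are also known to raise. These 8 lists had the same counts when adjusted over the list alone.

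The p53 targets had 5 higher and 8 lower of 24, or 6 and 8 when adjusted over the list alone (camera adjusted p = 0.495). Senescence-associated secretory genes had 3 higher and 5 lower of 18, or 3 and 6 when adjusted over the list alone (camera adjusted p = 0.653, lower, with a median of 0.03 and a mean of −0.10). Hypoxia and glycolysis genes had 2 higher and 4 lower of 24, also when adjusted over the list alone (camera adjusted p = 1, lower, with a median of 0.03 and a mean of −0.02). Cell adhesion and extracellular matrix genes had 6 higher and 10 lower of 29, or 6 and 11 when adjusted over the list alone (camera adjusted p = 0.228). Tenascin C (TNC) rose from 21.28 ± 1.90 to 39.33 ± 7.43 CPM (SD, n = 3 each).

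Genes whose 3′ UTR holds TCATCCA were lower in knockdown. The median log2 fold change was −0.20 for 320 genes with the word followed by A (95% bootstrap interval −0.24 to −0.16) and −0.08 for 1112 other genes with the word (−0.11 to −0.07). It was 0.03 for 8041 genes without CATCCA, the last 6 bases of the word (0.03 to 0.04). Of 1432 genes with the word in the 3′ UTR, 38.8% were called lower, against 16% of 10640 searched genes without it. The word was present in 24.5% of the 2262 searched genes called lower, and in 36.6% of the 295 called lower by 1.5-fold or more. Of the genes named above, beside those already marked, PCGF3, SUZ12, SOX9 and DKK3 hold the word and fell. OAS2, IFIT1 and IFI44L hold it and rose, and they are among 8 of the 35 tested interferon list members that hold it. CDKN1A holds it and did not pass (log2 fold change −0.05, edgeR adjusted p = 0.426). Leaving out the genes with the word left 3862 changed genes, 1956 higher and 1906 lower. The genes left still include related matches. Of 652 genes with CATCCA followed by A but not the word, 33.4% were called lower (median −0.08). Of 1373 genes with the word only in the coding sequence, 26.6% were called lower. This compares with 10.8% of 6591 genes with neither CATCCA in the 3′ UTR nor the word elsewhere. These intervals are over genes, which are not independent replicates.

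**Figure D4:**
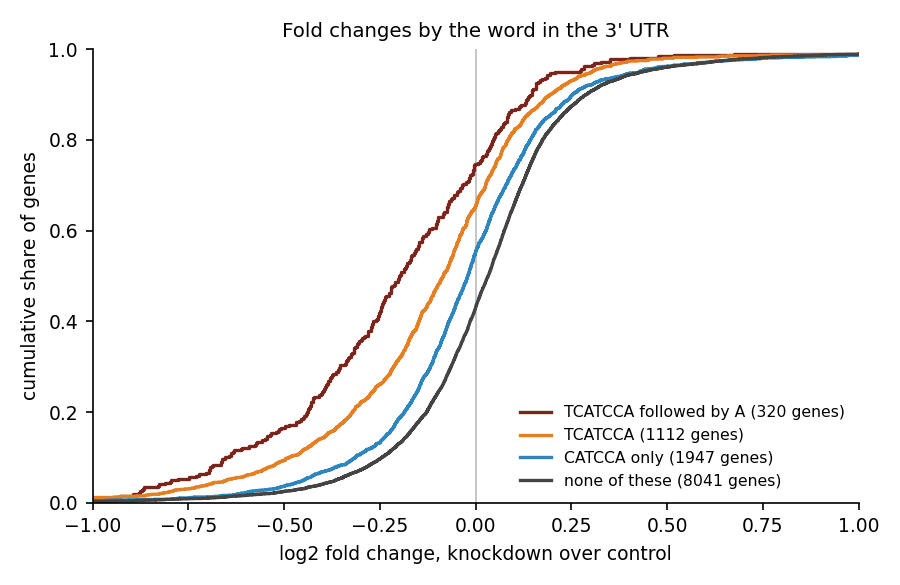
Cumulative share of genes by log2 fold change of knockdown over control, between −1 and 1, for searched genes grouped by the match to TCATCCA or its last 6 bases in their 3′ UTR. The curves of 320 genes with TCATCCA followed by A and of 1112 genes with TCATCCA lie to the left of the curve of 8041 genes without CATCCA, the last 6 bases.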

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

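Removal of the length and GC trend, camera on ranks, and the 2 removals of genes were chosen after the data were seen; the other alternatives were planned. COMMD3 stayed lower and past the threshold in all 15 refits, with log2 fold changes from −1.45 to −1.30, and BMI1 stayed short of it. COMMD3-BMI1 was at 0 counts, so no alternative gave it a value. For the other named genes no direction reversed, but 12 of them lost their call in 1 or more settings, 34 times in all: IRX2 in 8, SNX6 in 6, MLLT10 and CDKN1B in 5 each, GJA1 and RPLP2 in 2 each, and KDM2B, CDKN2A, COMMD7, COMMD10, PHLDA1 and PFKP in 1 each. The count of changed genes fell from 4545 to 2877 under DESeq2 (1179 higher), to 2943 at an adjusted p under 0.01 (1224 higher), and to 668 at 1.5-fold or more (317 higher and 351 lower), the last 2 by construction; for DESeq2 the cause was not tested. Without 1 library it was 3608 to 4297 (1606 to 1964 higher, 1949 to 2333 lower). Library-size scaling gave 4693, with 2505 higher and 2188 lower. The list calls went from 8 to 0 with an estimated correlation and to 17 under fry, which asks whether a list moves and not whether it moves more than other genes, and were 7 to 9 without 1 library. Whether same-numbered libraries pair was not settled: their deviations from the group means correlated by 0.079, 0.0055 and 0.071, against −0.1 to 0.039 for the 6 other pairs, and control replicate 2 correlated best with knockdown replicate 1 (0.039). With the replicate block 5248 genes and 8 lists were called.

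The reversals were in lists that were not called before or after, and the cause was not tested. Their adjusted p-values, given as the range over all 6 refits where 1 library was left out, were, for hypoxia and glycolysis, 0.967 with the replicate block, 0.999 with RLE and with the CPM filter, 0.953 with library-size scaling, 0.987 on ranks, 0.977 without the interferon list in the background, and 0.691 to 0.991 without 1 library. For BMP and TGF-beta targets they were 0.278 under fry and 0.78 to 0.991 without 1 library, for NF-kB 0.991 with the block, 0.987 on ranks and 0.824 to 0.991 without 1 library, for endoderm 0.655 under fry and 0.831 to 0.991 without 1 library, for Notch 0.559 to 0.917 without 1 library, for WASH and retromer 0.783 under fry, and for mesenchymal markers 0.971 without genes that hold the word. At this depth, edgeR recovered 60% of simulated 1.2-fold changes, so changes of that size can be missed.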

Other observations

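The post hoc lists and the tests of patterns here were chosen after the results were seen, apart from the counts over other splits. The genes named here were chosen after their values were seen. Beside the interferon list, genes of class I antigen presentation rose. Of 19 tested, 17 were higher (camera adjusted p = 1.14e-12; adjusted p = 0.0381 with an estimated correlation, over 5 added lists), and none of the 19 is on the interferon list. HLA-C rose from 1.96 ± 0.323 to 33.2 ± 7.76 CPM, the peptide transporter gene TAP1 from 1.80 ± 0.447 to 28.92 ± 5.90 CPM, and NLRC5, which drives class I transcription, from 0.465 ± 0.0493 to 6.07 ± 1.96 CPM (SD, n = 3 each). HLA class I genes are near-identical copies, so their separate levels are uncertain. PSMB9, an immunoproteasome subunit, had 1 control and 62 knockdown counts, a ratio of 61.1 (95% counting interval 10.6 to 2450). Of 10 class II genes, 4 were tested and 1, CD74, was higher (camera adjusted p = 0.472), while HLA-DRA and the class II activator CIITA had 0 counts in all 6 libraries.

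Among 14 tested RNA and DNA sensors and adaptors, 3 of them also on the interferon list, 8 rose and 1 fell (camera adjusted p = 2.77e-06; adjusted p = 0.0381 with an estimated correlation). DDX58, which encodes the RNA sensor RIG-I, rose from 13.3 ± 0.987 to 154.9 ± 23.1 CPM, and its adaptor MAVS fell from 209.3 ± 4.54 to 162.1 ± 5.98 CPM (SD, n = 3 each). The 3′ UTR of MAVS holds TCATCCA and that of DDX58 does not. That of IFIH1, also an RNA sensor gene, holds it too, though IFIH1 rose from 2.045 ± 0.638 to 42.14 ± 8.17 CPM. IFNB1, which encodes interferon beta, was too low for the filter: it had 0 counts in control and 3, 4 and 5 in the knockdown libraries. Against a floor of 3 control counts this was 3.94-fold higher or more, with the 12 knockdown counts taken as they are. No other interferon gene was tested either. Both tested chemokine genes of 6 were higher: CCL5 had 0 control and 164 knockdown counts, at least 53.9-fold higher, and CXCL10 had 2 and 103, a ratio of 50.8 (95% counting interval 13.7 to 425). Of 13 tested endothelial-associated genes, 9 fell (camera adjusted p = 8.88e-05; adjusted p = 0.117 with an estimated correlation), among them CDH5 from 15.21 ± 2.51 to 7.77 ± 0.777 CPM and TIE1 from 27.62 ± 0.447 to 14.19 ± 2.95 CPM. Of 4 tested leukocyte markers, 2 fell (camera adjusted p = 0.0394; adjusted p = 0.246 with an estimated correlation).

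The rise of interferon response genes was weighed against RNA from leukocytes and the scaling of the libraries. The tables argue against leukocytes, for the 14 markers looked at. Of these, 9 had a summed count under 10 over the knockdown libraries, and none of the 4 tested was higher. The sum over the interferon list went from 767.7 to 4619 CPM. The 10 markers too low to be tested summed to 1.613 CPM in knockdown and 1.624 in control. That low sum adds little, since a marker raised in knockdown would have passed the filter and left this set. The summed CPM of all 14 markers differed by −14.1, with every knockdown library (31.2 to 33.9) below every control library (43.7 to 51.5). Most of that sum came from the 4 tested markers, which were already present in control cells, so its fall says little about leukocyte RNA. The tables also argue against scaling, since the TMM factors ran from 0.9797 to 1.015 against a median rise of 15.7-fold over the list. The 34 members that stayed called as higher under each of 3 other scalings add little to this, as so large a rise could hardly be undone by scaling. A response to the knockdown reagent or its delivery, rather than to lower COMMD3, cannot be told apart from the knockdown, because the design has 1 knockdown group and no second reagent or rescue. Both that and a response to lower COMMD3 or COMMD3-BMI1 stay open, and the latter was untested.

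The fall of genes with TCATCCA in the 3′ UTR gave the lowest z of 16384 words, −16.09, against −5.086 for the lowest word that shares no 4 bases in a row with it. The tables argue against 3′ UTR length and base composition, since the lowest z of 196 words of the same letters was −2.481. They also argue against chance among words, since −16.09 lies far below −5.086. The lowest z in 100 shuffles of the fold changes was −4.597. Shuffling treats genes as independent, so this limit may be too narrow, and −5.086 also falls below it. A candidate explanation is repression through the seed of a short guide RNA, which predicts a stronger fall for sites in 3′ UTRs than in coding sequence and for more copies, and it stays open. With the word chosen in one random part of the genes and log2 fold changes, adjusted for length and GC content, compared in the other part, genes with the word in the 3′ UTR differed from those with it only in the coding sequence by −0.104 (95% interval −0.14 to −0.0679; the word chosen was CATCCAA, which overlaps TCATCCA) and, with the parts exchanged, by −0.0676 (−0.101 to −0.034; TCATCCA), while 2 or more copies against 1 gave −0.0803 (−0.165 to −0.00129) and −0.057 (−0.125 to 0.0159), the last not excluding 0, and genes with the word only in the coding sequence differed from genes without it by −0.0535 (−0.08 to −0.0239) and −0.0865 (−0.108 to −0.0636). The word TCATCCA occurs once in the COMMD3 transcript, in coding exon 2 on chromosome 10 from 22317885 to 22317891 (GRCh38), an exon shared with COMMD3-BMI1. Of all 7-base words, 7.617% occur in that transcript. CATCCAA, with a z nearly as low (−15.19), does not, so the match to COMMD3 depends on which of the overlapping words is taken. A guide against this site may be the source, but the guide sequence is not known here and an endogenous microRNA was not tested.

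The listing of COMMD3-BMI1 at 0 may come from counting that leaves out reads over exons of more than 1 gene, or from counting that gives them to 1 of the genes. Of 53 protein-coding genes with no exclusive exon base on their strand, 35.849% were at 0 in all 6 libraries, against 16.233% of 18351 genes with mostly exclusive bases (Fisher's exact test, two-sided, p = 5.11e-04, over genes, which are not independent). On GENCODE v29 the other 34 of the 53 had counts, which goes against leaving out all such reads. EIF4A1 goes against it too, since it has 290 exon bases of its own in GENCODE v29 and was at 0 while SENP3-EIF4A1, with 15.402% of its bases to itself, had 16778 counts in control, and 90 of 122 readthrough symbols whose parts are both listed had counts. The annotation behind the counts is not known here, so neither is settled, and a lack of the readthrough transcript in these cells stays open as untested too.

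The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. For the counts of changed, higher and lower genes 1 split, the real one, reached its own count (4545, 2084 and 2461), and the highest other split called 0 genes by edgeR, with at most 312 at an unadjusted p under 0.05 against 5842 in the real split. Each other split has libraries of both groups on each side, so the difference between groups widens the spread within a side and lowers these counts. The counts of the other splits are therefore not a measure of chance calls. For the gene lists 2 splits called 8, the real one among them. The 9 other splits, which mix the groups, called between 3 and 8 lists each with the preset correlation.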
